A study of Mus musculus with 6 samples.

How the data were processed

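RNA sequencing values were taken for 6 libraries of MC38, a mouse colon tumour cell line, all from a derivative called M1E5 in the genotype labels. The genotype labels put 3 libraries in the WT group and 3 in the group Zfx F5. Per the series' design text, Zfx was targeted by transfecting CRISPR ribonucleoprotein complexes with a lipid reagent, and the knockout was checked by PCR. Replicate numbers were given in accession order, name libraries only and pair nothing across the groups. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

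The labels describe the RNA source in 2 ways. The series' design text speaks of cells cultured in vitro, a column kit for RNA and 1 µg of RNA for sequencing, while the labels' extract protocol speaks of sorted tumour cells and another kit. Per the labels' protocols, 150 pg of cDNA entered Nextera XT library preparation, and single-end reads of 50 bases were made. The deposited table's own name says in vitro, which goes with the cultured cells of the design text. Which kit and which input were used for these libraries is not given in the sources used here. The Nextera XT preparation does not mark strand, so if it was used, reads of antisense or overlapping genes cannot be assigned to either partner. Reads of 50 bases also place genes with near-identical copies, such as ribosomal protein genes with many pseudogenes, mitochondrial genes with nuclear copies, and class I histocompatibility genes, with less certainty. The submitters' processing notes list the builds mm10 and GRCh38. The aligner, the counting program and their settings are not given in the sources used here.

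The deposited table holds log2 values for 52636 genes, called normalized in the table's own name; how the authors normalized them is not given in the sources used here. Its unit was worked out from the values. All 6 columns share a lowest value of -4.82, and after undoing the log2 and subtracting that floor each column summed to 1000000, which makes the deposited log2 values log2(CPM + 0.0353). One read then corresponds to a fixed CPM step in each library. For values of up to 300 reads, 100% came out whole within 0.05 read in each library, and each value was rounded to the nearest whole read. Values above 300 reads were rounded in the same way without this check. The recovered depth was 18876673 to 24241864 reads per library, and 1 read was worth 0.0413 to 0.0530 CPM. A count of 0 in a library allows a level of up to 3 reads, which is 0.124 to 0.159 CPM depending on the library. Intervals from read counts cover counting error only, since PCR copies were not marked by molecular identifiers. The deposited size column, also the authors', equals the summed exon length for all 52636 genes. Every row names a gene, and 0 sample columns of the table were left unused.

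Gene positions are those of mm10, from the GENCODE M21 annotation matched on gene identifiers. Of the 52636 identifiers, 52403 were matched, and for 51865 the exon coordinates in the table lay inside the annotated gene. There are 202 rows that share a symbol with another row. Both gene models of such a symbol enter a list.

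The comparison was made with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a linear model of group, a variance trend, robust moderation, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Genes were kept at a mean log2 value of at least 0 over the 6 libraries, which left 12279. A fold change is on the log2(CPM + 0.0353) scale and understates the change of genes with few reads. For the genes with the largest differences, the ratio of pooled CPM is given with an exact Clopper-Pearson 95% interval as well. A single gene in 3 against 3 libraries cannot reach an exact permutation p below 0.1. Differences are given as the libraries labelled Zfx F5 minus WT.

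Fixed gene lists, 44 in number, were tested with camera in limma at a preset correlation of 0.01 where at least 3 members were kept, which gave 38 tests adjusted together. The alternatives were camera with an estimated correlation, which compares a list with other genes allowing for its own correlation, and fry, whose p-value tests whether the genes of a list move on balance to one side without comparing them with other genes.

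The groups, the tests, the lists, the alternatives and the rule for naming genes were written before the data were examined. The rule takes Zfx and its family, the 10 largest higher and 10 largest lower genes, the leading members of each list, and the genes next to Zfx. For the largest differences it takes genes past the threshold whose groups do not overlap, with a higher group mean at least 3 log2 units above the filter, leaving out gene models without a name of their own. From each list it takes up to 4 members past the threshold with the largest differences, or 2 by level where none passes. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

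The fit was tested on simulated counts drawn from the means and depths of these libraries, with 200 genes changed. Over the 12388 genes kept in that step, 78% of 50 genes changed 1.25-fold, 94% of 50 changed 1.5-fold and 100% of the genes changed 2-fold or 4-fold were called with the right sign, and 5.58% of the calls were false. Every simulated gene had the same dispersion, 0.00134, and most were unchanged. In the measured data most genes were called, so these shares describe the simulated setting only. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per gene of 2.08 to 3.73 where 1 stands for sampling noise alone, so no pair looked like a library deposited more than once. This does not show that the libraries came from separate cultures.

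The alternatives tried were no filter and a stricter filter at a mean log2 of 2, added pseudocounts of 1 and 5 CPM, median centring, quantile normalization, TMM scaling, limma without trend and robust moderation, array weights, and leaving out each library in turn. Count models had been planned only for count data and were not run, because the deposited unit is log2. In their place limma voom was run on the recovered reads, an alternative chosen after seeing the data. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.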

Results

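The data are gene expression values from 6 RNA sequencing libraries of MC38, a mouse colon tumour cell line. The series' design text and the deposited table's own name speak of cells grown in vitro, whereas the extract protocol speaks of sorted tumour cells. There were 3 libraries with the genotype M1E5 WT and 3 with the genotype M1E5 Zfx F5, a line in which Zfx was targeted with CRISPR ribonucleoprotein. Zfx encodes a zinc finger transcription factor of the X chromosome. The WT libraries held 23365097, 18876673 and 24241864 reads and the libraries labelled Zfx F5 held 21191541, 19759239 and 22748778. Between 18656 and 19943 genes had at least 1 read in a library. The series implies a single comparison, which asks which genes differ in the Zfx-targeted cells. Values below are means of 3 libraries per group, with the standard error (SE) of the log2 difference from limma.

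Zfx mRNA was higher, not lower, in the libraries labelled Zfx F5. The gene (ENSMUSG00000079509, minus strand, mm10 chromosome X from 94074631 to 94123702) measured 64.4, 69.7 and 68.9 CPM in the WT libraries. In the libraries labelled Zfx F5 it measured 125, 129 and 122 CPM. The log2 means were 6.08 ± 0.06 (SD, n = 3) and 6.97 ± 0.04 (SD, n = 3), a difference of 0.89 (SE 0.042) or 1.86-fold, with a limma adjusted p of 3.47e-18. The 2-sided exact permutation p for Zfx was 0.1, the smallest that 20 assignments of 3 and 3 libraries allow. Between 1315 and 2777 reads per library lay behind these values. The design text speaks of a knockout. This rise neither shows nor excludes one, so the groups are named by their labels throughout. Gene-level values count reads over the whole gene and do not show whether a part of it is missing. The relatives Zfy1, Zfy2 and Zfp711 had 0 or 1 read in each library. The kept neighbours of Zfx differed less: Pdk3, a pyruvate dehydrogenase kinase gene, was 1.20-fold higher (limma adjusted p = 3.52e-05), and Eif2s3x, a translation initiation factor gene, had a log2 difference of 0.21 (SE 0.098) that did not pass (limma adjusted p = 0.0585).

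**Figure D1:**
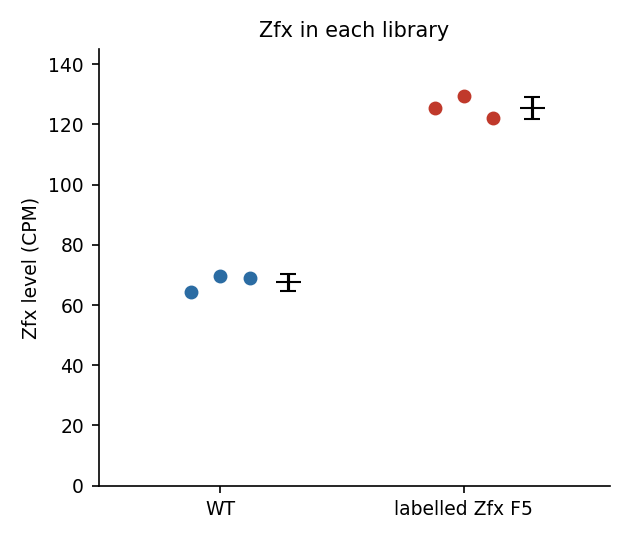
Zfx level in CPM (y axis) in the WT libraries and the libraries labelled Zfx F5 (x axis); points are libraries and the black marks show the mean and SD of 3. The WT libraries lie between 64.4 and 69.7 CPM and the libraries labelled Zfx F5 between 122 and 129 CPM.

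The difference between the groups was broad. Of 12279 kept genes, 8953 (72.9%) passed the adjusted threshold in limma, 4546 higher and 4407 lower in the libraries labelled Zfx F5. The order of these 2 counts is not stable: it turned round with TMM scaling (4195 higher and 4697 lower) and with the stricter filter (4036 and 4042). The groups did not overlap for 9124 genes (74.3%), where chance gives 10% for 3 against 3 libraries. At least 2-fold differences were found for 1240 genes, 505 higher and 735 lower, and at least 4-fold ones for 120 higher and 214 lower. The median log2 difference over all kept genes was 0.02. The count of 2-fold genes depends on low values: it was 2454 without a filter, with more genes higher (1378) than lower (1076), 825 with the stricter filter and 571 with 5 CPM added. The samples used here hold 1 edited clone, F5, although the series title speaks of clones, so any difference of F5 from the WT line that is unrelated to the edit enters this count as well. The direction of each difference rests on group labels that the level of Zfx could not check.

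The genes that fell furthest were nearly silent in the libraries labelled Zfx F5. Mvb12b, a subunit of the endosomal ESCRT-I sorting complex, had 5590 reads over the WT libraries and 4 over the others, a ratio of pooled CPM of 1339 (95% counting interval 523 to 4916). Zfp532, a zinc finger gene, had 3129 against 12 reads (250-fold lower, interval 143 to 484). Ppp1r9a, which encodes the actin-binding protein neurabin, had 1456 against 5 (279-fold lower, interval 119 to 861). Mid2, a tripartite motif gene of the X chromosome, had 1976 against 9 reads (210-fold lower, interval 111 to 461). Irx1, an Iroquois homeobox gene, had 1150 against 5 (220-fold lower, interval 94.2 to 680). Tmem117, Cplx2 (a regulator of synaptic vesicle fusion), Adcy3 (an adenylyl cyclase), Nexn (an actin-binding protein) and Zc3h12c followed, with ratios between 65.1 and 86.3 and at most 12 reads in any library labelled Zfx F5.

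Bche and Lyz2 were among the 10 genes that rose furthest under the naming rule, whose level limit leaves out Oas2 (log2 difference 5.50). Bche, which encodes butyrylcholinesterase, went from 7 to 583 reads (86.9-fold, interval 41.9 to 217). Lyz2, a lysozyme gene typical of myeloid cells, went from 29 to 976 reads (35.1-fold, interval 24.3 to 52.7). Aqp1, a water channel, rose from 2.96 to 88.1 CPM (log2 difference 4.88, SE 0.077) and Lgals9, which encodes galectin-9, from 1.38 to 36.8 CPM (4.73, SE 0.139). Lox, the collagen cross-linking enzyme lysyl oxidase, rose from 10.3 to 184 CPM (4.16, SE 0.062), and the matrix proteoglycan gene Bgn from 22 to 580 reads (27.5-fold, interval 18.0 to 44.3). Cdc42ep5, an effector of the GTPase Cdc42, went from 36 to 650 reads (18.8-fold, interval 13.5 to 27.1). Ifit1, Oasl2 and Rtp4 complete the 10 and belong to the interferon list.

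**Figure D2:**
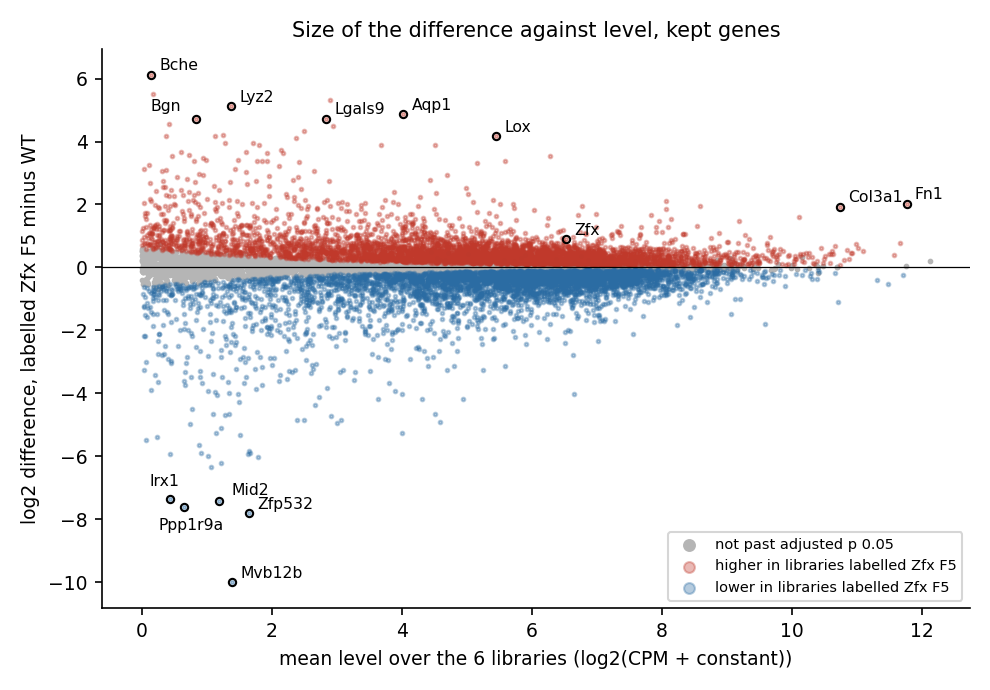
Log2 difference, libraries labelled Zfx F5 minus WT (y axis), against the mean log2(CPM + 0.0353) over 6 libraries (x axis) for 12279 kept genes; red and blue points passed the adjusted threshold and grey points did not. Lower genes reach a log2 difference of -10.01 (Mvb12b) and higher genes 6.13 (Bche), while Zfx lies at 0.89.

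Interferon response genes rose together in the libraries labelled Zfx F5. Of 37 kept members, 34 were higher and 3 lower in limma, and 27 were at least 2-fold higher. The list passed camera (adjusted p = 1.58e-12) and did so with an estimated correlation (adjusted p = 0.0347). The antiviral genes Ifit1 and Oasl2 rose from 106 to 2323 reads (22.9-fold, interval 18.8 to 28.1) and from 81 to 1607 reads (20.7-fold, interval 16.6 to 26.2). Rtp4, a chaperone gene induced by interferon, rose from 32 to 590 reads (19.2-fold, interval 13.5 to 28.4), and Oas2, a sensor enzyme of double-stranded RNA, from 9 to 482 reads (55.9-fold, interval 29.2 to 123). The 3 lower members, named after their values were seen, were Trim25, Socs1 and Ifih1, with log2 differences of -0.38 (SE 0.034), -0.33 (SE 0.126) and -0.20 (SE 0.088). With median centring Ifih1 no longer passed (limma adjusted p = 0.0825). Of the 3 kept markers of myeloid cells, Lyz2 rose alongside the list, while Cd68 (2.59 and 3.18 CPM) and Cd14 (9.36 and 8.39 CPM) did not pass. The 2 kept endothelial markers rose as well, Pecam1 from 8.79 to 26.1 CPM and Egfl7 from 4.35 to 9.70 CPM.

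**Figure D3:**
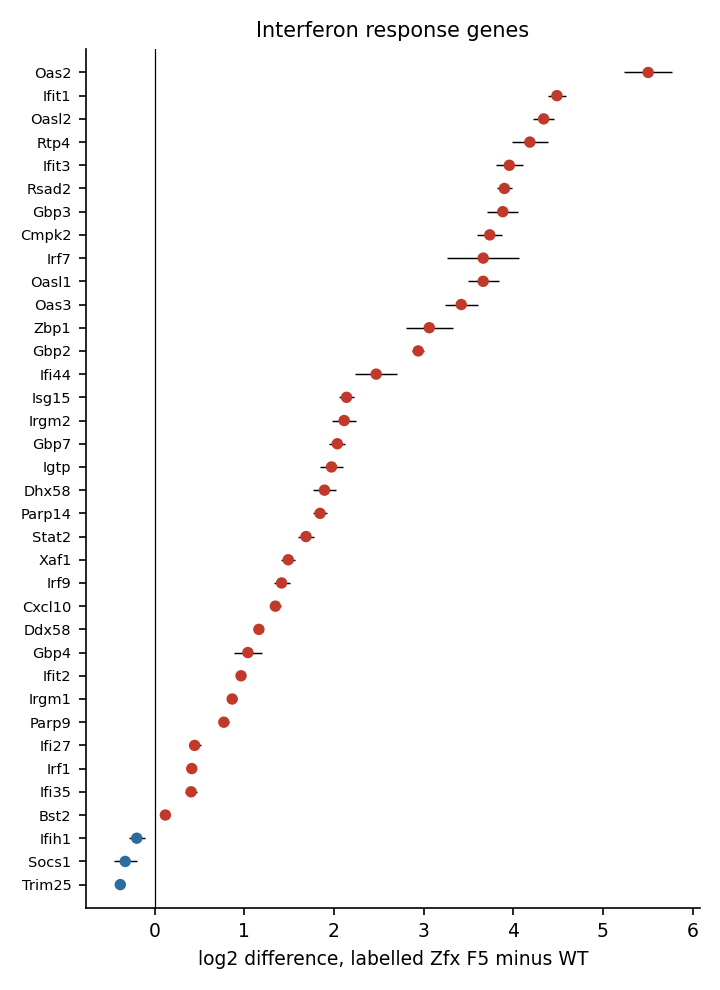
Log2 difference, libraries labelled Zfx F5 minus WT (x axis), of kept interferon response genes (y axis); points are limma estimates from 3 libraries per group and lines show the SE. Of the genes drawn, all but Trim25, Socs1 and Ifih1 lie above 0, with Oas2 at 5.50.

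Other immune lists moved less uniformly. For class I antigen presentation, 14 of 20 kept genes rose, 4 fell and 2 did not pass, which passed camera (adjusted p = 0.00159) but not with an estimated correlation (adjusted p = 0.301). The leading members were immunoproteasome genes, Psmb9 (3.11-fold), Psmb10 (2.53-fold) and the activator subunit Psme1 (2.16-fold), with H2-M3 at 2.05-fold. The main class I chain genes, chosen after their values were seen, moved little: B2m had a log2 difference of -0.09 (SE 0.027), H2-D1 one of -0.08 (SE 0.033) and H2-K1 one of 0.17 (SE 0.031). With median centring B2m and H2-D1 no longer passed (limma adjusted p = 0.0508 and 0.136). Of 7 kept ligands of immune checkpoints and natural killer cells, 2 rose, 4 fell and 1 did not pass (camera adjusted p = 0.804). Lgals9 and Cd274, which encodes PD-L1 (2.20-fold), rose, while the ligand genes Pvr (2.04-fold) and Ulbp1 (1.27-fold) fell. Of 17 chemokine, cytokine and NF-kB genes, 6 rose, 9 fell and 2 did not pass (camera adjusted p = 0.715). The chemokine genes Cxcl1 and Ccl5 rose 6.88-fold and 5.65-fold, and the cytokine genes Il33 and Lif fell 6.32-fold and 3.15-fold. Of 12 genes for sensing cytosolic DNA and RNA, 6 rose and 4 fell (camera adjusted p = 0.397), with Zbp1 8.36-fold and Ddx58 2.24-fold higher and Mavs 2.07-fold lower. Of 2 kept class II genes, H2-DMb1 had a log2 difference of -0.22 (SE 0.096, limma adjusted p = 0.0444) and the other did not pass. The H2-DMb1 call was lost when adjusted over the list alone, without a filter (limma adjusted p = 0.0755), with median centring (0.0774), without trend and robust moderation (0.0641) and with array weights (0.0572). It was also lost without WT replicate 1 (0.171), without WT replicate 3 (0.0667) and without Zfx F5 replicate 3 (0.252).

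Most kept matrix genes rose and most kept Wnt target genes fell. In the extracellular matrix list 18 of 26 kept genes rose, 6 fell and 2 did not pass (camera adjusted p = 0.00217), a call that was lost with an estimated correlation (adjusted p = 0.270). Beside Bgn and Lox, the protease inhibitor gene Timp3 rose 10.4-fold, while Col18a1, a basement membrane collagen gene, fell 5.34-fold. Of the list's abundant members, chosen after their values were seen, Fn1 (fibronectin) rose from 1730 to 7058 CPM and Col3a1 from 874 to 3334 CPM. Fibroblast markers moved both ways beside the list, with Pi16 7.41-fold higher and Dcn, itself a matrix gene, 3.53-fold lower. Of 8 kept Wnt targets 7 fell and 1 did not pass (camera adjusted p = 0.00603; with an estimated correlation, adjusted p = 0.270). Apcdd1 fell 4.19-fold, the transcription factor gene Lef1 3.96-fold, Axin2 3.86-fold and the receptor ligase gene Znrf3 1.68-fold, and Axin2, Apcdd1 and Znrf3 all encode feedback inhibitors of the pathway. YAP and serum response targets had 11 of 17 higher and 5 lower (camera adjusted p = 0.0168; with an estimated correlation, adjusted p = 0.582; without trend and robust moderation, adjusted p = 0.0529), led by Ankrd1 (2.23-fold), Cyr61 (2.09-fold) and Amotl2 (2.04-fold).

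Lists for related states of the cells did not pass camera, although many members did in limma. In the TGF-beta list 9 of 22 kept genes rose and 11 fell (adjusted p = 0.746), with Id3 3.90-fold and the receptor gene Tgfbr2 3.65-fold higher and Thbs1 4.99-fold lower. Of 16 mesenchymal markers 8 rose and 8 fell (adjusted p = 0.897), with the transcription factor gene Snai2 10.0-fold and Pdgfra 3.14-fold lower and S100a4 2.78-fold higher. Only 3 of 27 epithelial genes were kept, 1 higher (Cdh1, 0.848 to 2.10 CPM) and 2 lower (adjusted p = 0.897). Of 8 hedgehog and notch genes 2 rose and 5 fell (adjusted p = 0.746), among them Notch1 (1.81-fold lower).

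In the lists of lipid, sugar and mitochondrial metabolism more members were higher than lower, by smaller factors. Cholesterol synthesis genes rose in 18 of 20 cases and did not pass in 2 (camera adjusted p = 5.93e-05; with an estimated correlation, adjusted p = 0.166), led by the enzymes Mvd (2.92-fold), Fdps (2.46-fold) and Nsdhl (2.11-fold). In glycolysis 14 of 18 kept gene models rose and 3 fell (camera adjusted p = 0.00240; with an estimated correlation, adjusted p = 0.277), led by the phosphofructokinase genes Pfkl (2.06-fold) and Pfkm (1.82-fold) and by Pkm (1.75-fold). Aldoa has 2 gene models in the table, of which the one at 377 CPM in WT rose 1.49-fold and one at 6.72 CPM fell 2.10-fold. Of 35 nuclear genes of oxidative phosphorylation 26 rose and 3 fell (camera adjusted p = 0.000215; with an estimated correlation, adjusted p = 0.527), with Atp5o, Ndufa4 and Ndufv1 each 1.54-fold higher. The TCA cycle list had 14 of 20 higher and 1 lower (camera adjusted p = 0.00252; with an estimated correlation, adjusted p = 0.527). Its largest rise was Idh1 (2.88-fold), which encodes the soluble NADP+ isocitrate dehydrogenase and not the NAD+ enzyme of the cycle. Idh3g, a subunit of the NAD+ enzyme, followed at 1.55-fold. Of 13 mitochondrial-encoded genes 7 rose and 6 did not pass (camera adjusted p = 0.00863; with an estimated correlation, adjusted p = 0.631; after quantile normalization, adjusted p = 0.291), with mt-Nd6 1.64-fold and mt-Nd2 1.52-fold higher. Fatty acid and lipid genes had 9 of 17 higher and 3 lower (camera adjusted p = 0.0825), with the desaturase gene Scd2 1.71-fold higher.

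In the ribosomal protein, ribosome biogenesis, and G2 and M phase lists more members were higher than lower, while S phase genes were split. Cytosolic ribosomal protein genes rose in 33 of 45 cases and fell in 1 (camera adjusted p = 5.93e-05; with an estimated correlation, adjusted p = 0.424), with Rpl15 1.81-fold higher. Many of these genes have near-identical pseudogenes, so their levels are uncertain, and Rpl19 was listed at 0.861 CPM in WT. Myc targets in ribosome biogenesis had 17 of 23 higher and 3 lower (camera adjusted p = 0.00177; with an estimated correlation, adjusted p = 0.270), with the pyrimidine synthesis gene Cad 1.73-fold and nucleolin gene Ncl 1.45-fold higher and Nop56 1.40-fold lower. G2 and M phase genes had 20 of 30 higher and 3 lower (camera adjusted p = 0.00240; with an estimated correlation, adjusted p = 0.270), with the mitotic regulators Cdc20 1.58-fold and Plk1 1.51-fold higher. S phase genes had 7 of 26 higher and 8 lower (camera adjusted p = 0.746), with the ribonucleotide reductase gene Rrm2 1.58-fold lower. Amino acid and integrated stress response genes had 15 of 23 higher and 3 lower (camera adjusted p = 0.00159; with an estimated correlation, adjusted p = 0.387). The cystine transporter gene Slc7a11 rose 1.87-fold and Cth 1.85-fold, whereas the stress transcription factor genes Ddit3 and Atf3 fell 1.95-fold and 1.83-fold.

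Genes reported in earlier work as Zfx targets in stem and leukaemia cells were mostly lower in the libraries labelled Zfx F5. Of 9 kept, 8 fell and 1 rose in limma, but the list did not pass camera (adjusted p = 0.134; with an estimated correlation, adjusted p = 0.559). It passed without the filter on low values (adjusted p = 0.0372). Ptpmt1, a mitochondrial phosphatase gene, fell 1.54-fold, the cyclin gene Ccnd1 1.31-fold and Tbx3 1.24-fold, and the hedgehog effector gene Gli1 rose 1.87-fold. The remaining falls, named after their values were seen, were small: Fkbp1a 1.20-fold, Ptch1 1.12-fold, Idh2 1.11-fold, Clic1 1.09-fold and Myc 1.06-fold. In the list of genes near Zfx on the X chromosome, which counts Zfx itself among the higher ones, 6 of 13 were higher and 3 lower (camera adjusted p = 0.387). Las1l rose 1.90-fold and Zxdb fell 2.41-fold.

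**Figure D4:**
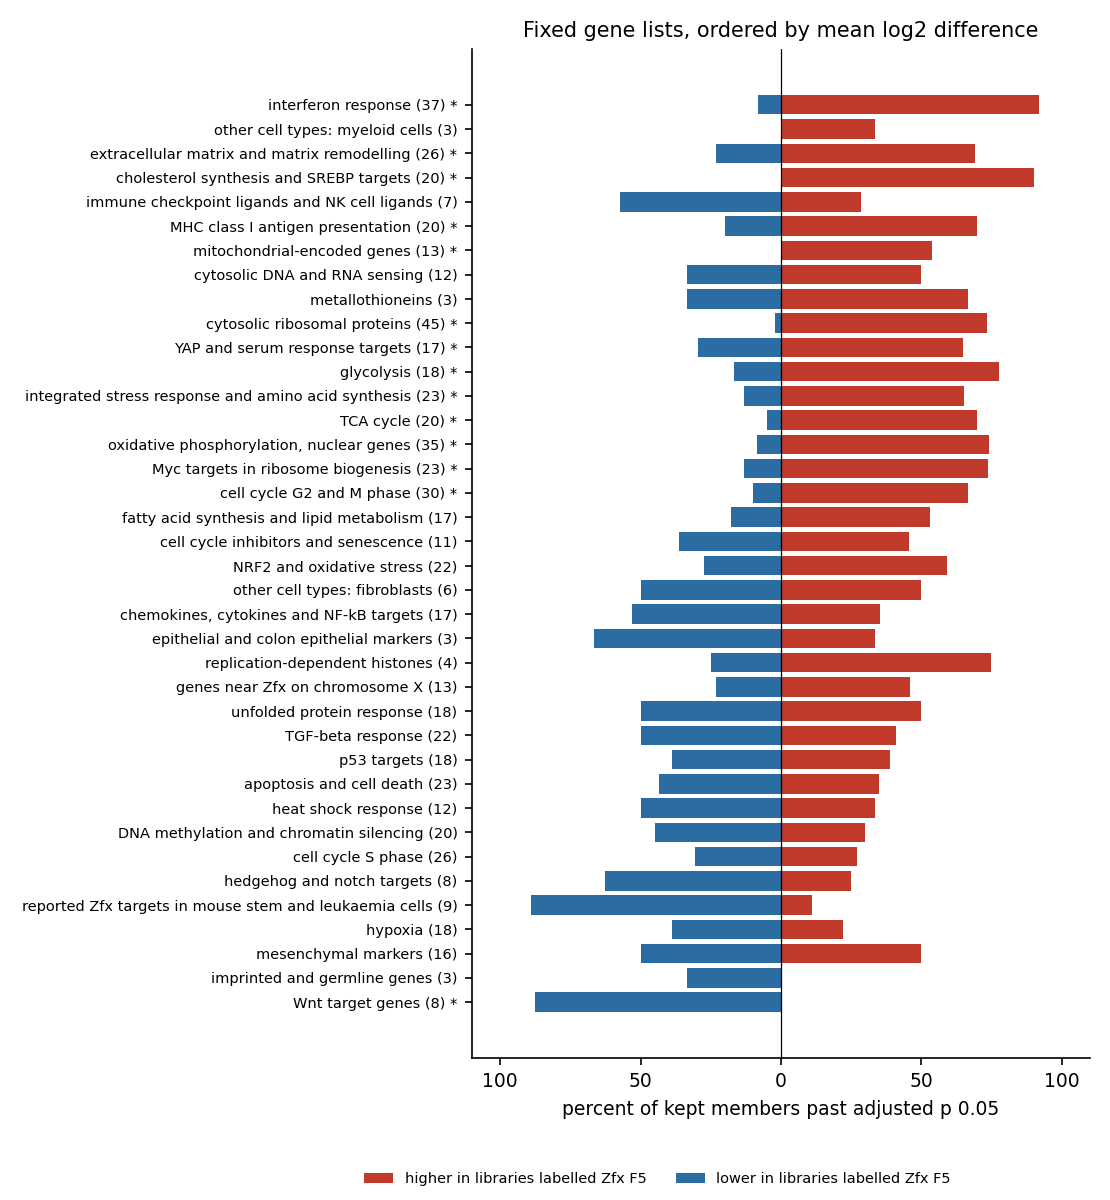
Percent of kept members past the adjusted threshold (x axis), higher to the right in red and lower to the left in blue, for the 38 lists tested (y axis, kept members in brackets); a star marks the 14 lists that passed camera at a preset correlation. Interferon response is at the top with 34 of 37 higher and Wnt targets at the bottom with 7 of 8 lower.

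Most markers of other cell types lay below the filter, except in the fibroblast list, where 6 of 11 were kept. No T and NK cell, B cell, or Y-linked and X-inactivation gene of the lists was kept. Of 18 myeloid markers 3 were kept, of which only Lyz2 passed (camera adjusted p for the list 0.469). Of 6 kept fibroblast markers 3 rose and 3 fell (camera adjusted p = 0.897), Pi16 (7.41-fold) and Col3a1 (3.82-fold) higher and Pdgfra (3.14-fold) and Dcn (3.53-fold) lower. Of 11 endothelial markers 2 were kept and both rose, Pecam1 2.96-fold and Egfl7 2.23-fold.

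The other lists did not pass camera. NRF2 and oxidative stress genes had 13 of 22 higher and 6 lower (adjusted p = 0.181), with Gstm1 4.04-fold and Nqo1 2.97-fold higher and Srxn1 2.07-fold lower. The p53 targets had 7 of 18 higher and 7 lower (adjusted p = 0.897), and cell cycle inhibitors 5 of 11 higher and 4 lower (adjusted p = 0.338), with Gas1 2.12-fold and Cdkn2b 1.89-fold higher. The unfolded protein response had 9 of 18 higher and 9 lower (adjusted p = 0.849), with the sensor gene Ern1 2.46-fold lower. Heat shock genes had 4 of 12 higher and 6 lower (adjusted p = 0.897), hypoxia genes 4 of 18 higher and 7 lower (adjusted p = 0.422), and apoptosis genes 8 of 23 higher and 10 lower (adjusted p = 0.897). Genes of DNA methylation and chromatin silencing had 6 of 20 higher and 9 lower (adjusted p = 0.746), with the methyltransferase gene Dnmt3a 2.02-fold lower. Metallothioneins had 2 of 3 higher and 1 lower (adjusted p = 0.397), histones 3 of 4 higher and 1 lower (adjusted p = 0.897), and imprinted and germline genes 1 of 3 lower, Plagl1 by 4.09-fold (adjusted p = 0.715). The counts adjusted over the list alone equalled those over all genes, except for 12 higher YAP and serum response targets, 6 higher S phase genes and 0 lower class II genes. The mean and the median had different signs in the checkpoint ligand, chemokine, TGF-beta, epithelial, apoptosis, imprinted and fibroblast lists, where members went both ways. In the mesenchymal list the mean and median were below 0 and the camera direction was up.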

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

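The voom fit on recovered reads was chosen after seeing the data; the others here were fixed before. It called 8948 genes, of which 8914 were shared with the 8953 reported. Over all alternatives the number of genes called ran from 8078 with the stricter filter, which tests fewer genes, to 10017 without a filter. Leaving out each library in turn gave 8546 to 8735 genes called, 4298 to 4459 higher, 4216 to 4306 lower, 1228 to 1260 at least 2-fold different and 14 lists passing. The number of genes at least 2-fold different moved from 1240 to 2454 without a filter, to 825 with the stricter filter and to 571 with 5 CPM added. The filters change which genes are tested and an added 5 CPM shrinks the fold of low genes by construction. The 14 lists that passed camera became 1 with an estimated correlation, the interferon response, and 31 lists passed with fry, which does not compare a list with other genes. The estimated correlation was -0.0608 for Wnt targets and 0.00470 for cholesterol synthesis, both under the preset 0.01. Correlated members therefore do not account for the loss of these lists, and the cause was not tested. In the other lists that were lost it was above 0.01. The share of calls that were higher, 50.8%, ran from 47.2% with TMM scaling to 54.7% with quantile normalization, so lower calls outnumbered higher ones with TMM, and higher ones led at 2-fold without a filter. Of 160 genes taken by the naming rule, without those chosen later, 4 changed side of the threshold under some alternative (Eif2s3x, H2-DMb1, Hist1h2bc and Tjp1; the cause was not tested), and none of these or the 15 lists followed reversed. No paired analysis was possible because the labels give no replicate numbers shared by the groups. Depth limits the genes near the filter, where 3 reads are worth up to 0.159 CPM.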

Other observations

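The tests of paralogs, exchanged labels, myeloid and endothelial transcripts, type I collagen with Dcn and Lum, scaling, and the ZFX motif against uncalled genes below, and the interferon signalling genes named here, were chosen after the results were seen. The tests of chromosomes, dominant genes, GC content, the segment holding Zfx, 7 fibroblast markers and the ZFX motif against all other kept genes were set before they were run. Of these, the segment and fibroblast marker tests address rises, of Zfx and of matrix genes, that were first seen in the results. Transcription factors that carry the interferon signal were higher in the libraries labelled Zfx F5: Stat2 rose from 7.97 to 25.7 CPM and Irf9 from 7.53 to 20.1 CPM. Irf7, an amplifier of the response, rose from 0.450 to 5.41 CPM. Of 6 interferon genes looked up, Ifna2, Ifna4, Ifng, Ifnl2 and Ifnl3 had 0 reads in each of the 6 libraries, which allows at most 0.159 CPM in the shallowest, and Ifnb1 had 0 reads in the WT libraries and at most 2 in a library labelled Zfx F5. The receptor gene Ifnar1 was lower, at 109 CPM in WT and 66.2 CPM in the libraries labelled Zfx F5 (log2 difference -0.72, SE 0.041). Its partner chain gene Ifnar2 was slightly higher, at 27.5 and 30.7 CPM (limma adjusted p = 0.0229), a call lost with TMM scaling (limma adjusted p = 0.0678). Mb21d1, which encodes the DNA sensor cGAS, fell from 61.3 to 39.6 CPM.

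Some genes were near-silent in the libraries of a single group. Among all genes of the table at 10 CPM or more in WT, 15 had at least 50 times lower pooled CPM in the libraries labelled Zfx F5, and the reverse was found for 0 genes at that level. At 1 CPM or more the numbers were 28 lower and 12 higher. These counts come from pooled reads and carry no test.

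The first pattern is the number of genes that differ, 8953. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; 1 split, the real one, gave this many and the highest of the others was 0. Chromosome explained 0.526% of the variance of the log2 differences (the highest of 1000 permutations was 0.433%), and 1 of 297 windows of 40 neighbouring genes had a median beyond 0.3, which argues against gains or losses of chromosomes in the clone as the main source. GC content and length together explained 1.77% of this variance, with Spearman correlations of 0.009 for GC content and -0.183 for length. A share of variance weighs large differences most, so it cannot show how many small calls a length trend adds. After TMM scaling 8892 genes were called, so a few dominant genes do not account for the number. Differences of the sequenced clone from its parent that are unrelated to the edit stay open, since the samples used here hold only the edited clone F5.

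The second pattern is the higher Zfx mRNA in libraries labelled as Zfx-targeted. A gain of the segment holding Zfx would raise its neighbours alike, but the 25 kept genes within 5 Mb had a median log2 difference of 0.0725 (95% interval -0.01 to 0.25). Reads counted for the paralogs Zfy1, Zfy2 and Zfp711 together held 0.0834% of the gain in Zfx CPM. This cannot decide on shared reads, since paralog reads placed on Zfx would be counted for Zfx. Zfa, another relative, is not in the deposited table. An exchange of a single library is not seen, as 0 of the 6 libraries correlated best with the other group (Pearson's r across genes was 0.997 in each pair within a group and 0.941 to 0.943 between groups). An exchange of all labels cannot be told apart from a gene whose mRNA rises after editing, because 0 libraries had Zfx at or under 3 reads and gene-level values do not show a small deletion; reads along Zfx in each library would decide between them.

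The third pattern is the rise of interferon response genes, Lyz2 and matrix genes; macrophages or other myeloid cells would bring their abundant transcripts, but Tyrobp, Fcer1g, Laptm5, Ctss, C1qa, C1qb, C1qc, Csf1r and Ptprc together reached 1.13% of the gain in Lyz2 CPM. The 2 kept endothelial markers Pecam1 and Egfl7 rose with the pattern, but Cdh5, Kdr, Tek, Tie1, Emcn, Vwf, Cldn5, Esam and Erg together reached 3.65% of the gain in Pecam1 CPM, which argues against endothelial cells. The 7 fibroblast markers set before (Dcn, Lum, Dpt, Pi16, Clec3b, Fap and Pdgfra) did not decide by level. Their median was 1.08 CPM in the libraries labelled Zfx F5, above the bound of 1 CPM, with Dcn and Pdgfra already at 120 and 247 CPM in WT. They also did not rise as a set by the matrix list's median log2 difference of 0.51, as set before for fibroblasts. Dcn, Lum, Dpt and Pdgfra fell (log2 difference -1.82, -1.75, -1.07 and -1.65), while Pi16 (2.89), Fap (0.39) and Clec3b (0.02) did not. Lum, Fap and Clec3b averaged 0.123 CPM or less in each group, under the worth of 3 reads, so their directions are uncertain. The median gain of Col1a1, Col1a2, Dcn and Lum was 0.0131% of the Col3a1 gain. Both type I collagen genes rose from low levels, Col1a1 from 0.188 to 0.942 CPM and Col1a2 from 0.0880 to 3.91 CPM. Their gains were 0.0306% and 0.155% of the Col3a1 gain, which argues against fibroblasts as its main source. Col3a1 stood at 3334 CPM in the libraries labelled Zfx F5. Scaling did not remove the interferon part, whose mean log2 difference was at least 2.06 under median centring, quantile normalization and TMM scaling, against 2.10 as reported. Over 16 settings, which also changed the filter, the added CPM or the libraries used, this mean ran from 1.08 to 2.31. A response of the tumour cells themselves, whether to the edit, to the transfection or to selection of a clone, therefore stays open as a hypothesis that this design does not divide further.

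A last hypothesis is that loss of an activating factor lowers genes whose promoters carry AGGCCT, the core of the motif reported for ZFX. The search covered the first 500 bases of the longest annotated protein-coding transcript of each gene, spliced, and not the sequence upstream of it. It found AGGCCT in 18.7% of 4125 lower protein-coding genes and 16.0% of the other kept ones, a ratio of 1.17. This ratio lay above the 0.875 to 1.08 of 11 control palindromes of the same base composition. Against the 2383 genes that were not called the ratio was 1.13, inside the controls' range of 0.869 to 1.15. For higher genes the ratios were 0.872 and 0.944, each below all 11 controls (0.945 to 1.14 and 0.981 to 1.248), the first over a comparison group that holds the lower genes. Among genes at least 2-fold lower and at least 2-fold higher the ratios to all other kept genes were 1.10 and 0.841, inside the controls' ranges (0.939 to 1.31 and 0.746 to 1.40). The 2 comparisons of all lower genes differ, so the hypothesis stays open. The level of Zfx mRNA could not check the labels on which each direction rests.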
